A study of Mus musculus with 23 samples.

How the data were processed

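Ventral prostate RNA of C57BL/6J mice was sequenced in 23 libraries, in 6 groups of diet (4 or 24 mg folic acid per kg) by state (intact, 3 d or 10 d after castration). Per the labels, mRNA was selected with oligo-dT beads, fragmented and copied from random hexamers, and an adaptor was ligated to the first strand. The authors' processing notes name bcl2fastq 2.17.1.14, Bowtie 0.12.9, RSEM 1.2.3 and the mouse genome build mm10. The deposited table holds expected counts per gene, the estimated numbers of reads that RSEM assigns, not scaled between libraries, for 20308 gene symbols. The strand used for counting, the gene annotation and the read length are not given in the sources used here. The table had 1 column that no sample label described, named as control 3 d replicate 2, which was not used. Of the values 19.5% were not whole numbers, and they were rounded, while 3398 genes had no count in any library. A shared read is divided between related genes by estimate, so values of close paralogs (Sbp and Sbpl, Ces1d and Ces1e, Amd1 and Amd2, Lyz1 and Lyz2, Spin2c and Spin2d) and of overlapping neighbours can trade counts.

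Genes were filtered with filterByExpr over the 6 groups (minimum count 10, minimum total 15), which left 13412, and scaled with TMM factors, which ranged from 0.553 to 1.70. One edgeR 4.0.16 quasi-likelihood model (robust fit, 1 mean per group) was fitted to all 23 libraries in R 4.3.3, with a biological coefficient of variation of 0.364 and 14.5 prior degrees of freedom. It tested 12 comparisons: 3 d and 10 d against intact and 10 d against 3 d on each diet, folic acid against control in each state and for the mean over the 3 states, and the diet by castration interaction at each time. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. A log2 fold change is given with its standard error, and levels are CPM scaled by the TMM factors, given as group mean and SD. Among the tested genes the median standard error of a log2 change lay between 0.285 and 0.31 for comparisons of 2 groups, at 0.171 for the mean diet effect and at 0.41 to 0.425 for the interactions.

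Before the data were examined, the comparisons, tests, alternatives, 30 gene lists and the rule for naming genes were fixed. The lists are prostate secretory and androgen-induced genes, genes known to rise after castration, steroid receptors and 5-alpha-reductases, folate transport and one-carbon metabolism, DNA methylation and demethylation, polyamine metabolism, cell cycle, cell death, secretory pathway and unfolded protein response, cholesterol and fatty acid synthesis, and the nuclear genes of the mitochondrial respiratory chain. The others are markers of castration-resistant proximal luminal cells, luminal and basal epithelium, smooth muscle, fibroblast and extracellular matrix, endothelium, macrophage, MHC class II antigen presentation, lymphocyte, neutrophil and mast cell, interferon response, seminal vesicle, urothelium, adipocyte, skeletal muscle, nerve and Schwann cell, red blood cell, immediate-early genes and the mitochondrial genome. Lists with at least 5 tested genes (25 of 30) were tested with camera of limma 3.58.1 at its preset correlation of 0.01, two-sided, with p adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance. For each list the members called are counted over all genes and adjusted over the list alone. Where a called list is said to move, its median, mean and test have the same sign, except for the proximal luminal list in the 3 d interaction, which is not reported on.

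Named in the castration comparisons were the called genes with a mean log2 CPM of at least 1 and no overlap between the libraries of both groups, the 8 with the largest change each way, or 5 each way for 10 d against 3 d, leaving out predicted and unnamed genes. In the diet and interaction comparisons the 8 called genes with the smallest p each way were named, or the 5 with the smallest p where none passed. Up to 4 members per list with the smallest p could be named, and 12 genes were named in advance, among them Pbsn, Sbp, Spink1, Fkbp5, Clu, Mki67, Folr1 and Dnmt1. Results of some genes are not reported here. Spink1 is listed as Spink3, and Folr1 was below the filter. Further members of a list, where 5 or fewer were called, were named after their values were seen. Positions are from GENCODE M21 on GRCm38 (mm10), in which 13338 of the 13412 tested symbols were found.

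The involution score of a library is the mean log2 CPM (prior count 2) of genes higher after castration minus that of genes lower, with genes chosen in a fit without diet (adjusted p under 0.05 and an absolute log2 change of at least 1 at both times). Score differences, and shares of counts, were tested with two-sided exact permutation tests of the diet or group labels, for which the smallest p of 4 against 4 or 4 against 3 libraries is 0.0286. Adjusted p values are over the 5 score tests and over the 7 group comparisons of each share. Exact binomial 95% intervals of shares cover counting error only, since reads without molecular identifiers are not independent molecules. Total counts, in M reads, ranged from 6.38 to 16, and from 3.23 to 11.2 without Sbp.

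The method was tested on simulated counts, drawn at random with each gene's mean level and dispersion from these data and the same mean in every group. Of the 13412 genes 200 were then changed in a single group, or in all folic acid libraries for the mean diet effect. The simulated data held no castration response, no shift of Sbp and no outlying library, so the rates need not hold for the real comparisons. A 4-fold change was called in 68.2% of cases at 3 d and 72.7% at 10 d on the control diet, 69.7%, 69.7% and 72.7% for diet in the 3 states, 90.9% for the mean diet effect, and 53.0% and 51.5% for the interactions. A 2-fold change was called in 23.9% and 46.3% after castration on the control diet, 29.9%, 28.4% and 31.3% for diet in the 3 states, 67.2% for the mean diet effect, and 13.4% and 4.48% for the interactions.

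Alternatives were library totals alone, RLE size factors, TMM without the 50 most abundant genes, no filter, a strict filter (CPM of at least 1 in at least 12 libraries), DESeq2 1.42.0, voom with quality weights, a fit that is not robust, a minimum absolute log2 change of 1, only the groups compared, the replicate number as a block, other genes in the score, and each library left out in turn. Added after the data were seen were the fit without 4 libraries, chosen from the list means per library (control intact replicate 2 for muscle transcripts, folic acid intact replicate 3 and folic acid 10 d replicates 2 and 3 for the extremes of stromal transcripts in their groups, the last of them within the range of the libraries kept) and the stromal score as a covariate. Pairs of libraries of a group were checked for duplicates, and none of the 33 pairs was one. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.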

Results

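Gene expression was measured by RNA sequencing in the ventral prostate of C57BL/6J mice. The mice were kept from before birth on a control diet with 4 mg folic acid per kg or on an enriched diet with 24 mg per kg. At 7 weeks of age the gland was taken from intact mice, or the mice were castrated, which removes testicular androgens, and the gland was taken 3 or 10 d later. The castrated mice were thus 3 or 10 d older than the intact ones when the gland was taken. None of the 6 groups was sham-operated or intact at that later age. Effects of androgen loss, of surgery and of age therefore cannot be told apart in the castration comparisons. The 23 libraries made 6 groups. There were 4 intact, 3 at 3 d and 4 at 10 d on the control diet, and 4 of each on the folic acid diet. The labels speak of RNA from 4 mice per group, so each library is taken as 1 mouse. The labels used here name no litter. Mice of a litter would share a diet given from before birth, so effects of litter and diet cannot be told apart. The tests treat each mouse as independent. A further column of the table, named as control 3 d replicate 2, had no sample label and was not used, so each comparison with control 3 d rests on 3 libraries. Total counts per library, in M reads, ranged from 6.38 to 16. Their means (± SD) were 13.4 ± 2.33 in intact, 11.3 ± 1.46 at 3 d and 9.42 ± 1.72 at 10 d on the control diet, and 11.5 ± 3.99, 9.66 ± 0.864 and 9.17 ± 2.39 on the folic acid diet. None of 7 comparisons of total counts between groups passed (two-sided exact permutation tests, adjusted p from 0.4 to 0.943).

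A single secretory transcript filled much of the intact libraries and shrank after castration. Sbp, the gene of the androgen-dependent spermine-binding protein of the ventral prostate (GRCm38, chromosome 17, 23941672 to 23945607), took 51.9% ± 1.22 of all counts (SD, n = 4) in intact mice on the control diet and 56.0% ± 4.61 (n = 4) on the folic acid diet. At 3 d its share was 30.8% ± 0.199 (n = 3) and 33.0% ± 5.80 (n = 4), and at 10 d it was 8.10% ± 1.39 and 11.3% ± 4.76 (n = 4 each). The 4 differences from intact were -21.1, -43.8, -23.0 and -44.8 percentage points. Each had an exact permutation p of 0.0286, the smallest that groups of this size allow, and an adjusted p of 0.05, which does not pass the threshold of under 0.05. Between diets the shares differed by 4.16 points in intact mice (exact permutation p = 0.143), 2.24 at 3 d (exact p = 0.543) and 3.17 at 10 d (exact p = 0.314). The counting error of a single library's share was at most 0.039 points on either side (exact binomial interval, 95%). The 20 most abundant genes together took 57.4% ± 0.903 and 61.3% ± 4.39 of intact libraries, 36.3% ± 0.283 and 38.4% ± 5.88 at 3 d, and 15.8% ± 1.78 and 18.6% ± 4.99 at 10 d, on the control and the folic acid diet. Reads shared by Sbp and its close relative Sbpl were divided between them by an estimate.

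**Figure D1:**
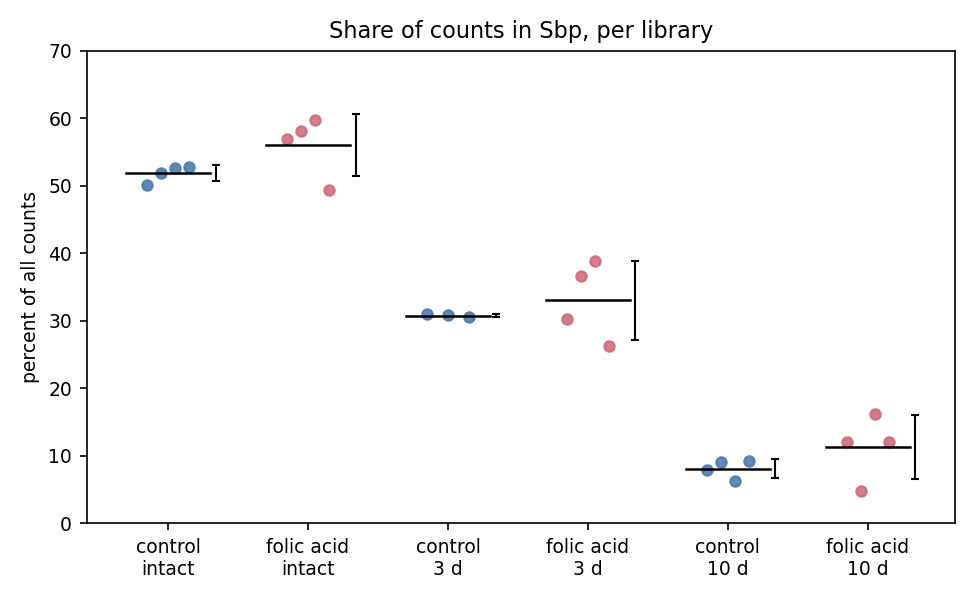
Percent of all counts assigned to Sbp in each library (points), by diet and state, with the group mean (line) and SD (bar). Group means went from 51.9% and 56.0% in intact mice to 8.10% and 11.3% at 10 d on the control and the folic acid diet.

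Because Sbp and a few other transcripts shrank, most other transcripts took a larger share of the sequenced counts. Log2 changes are therefore given relative to the bulk of the 13412 genes tested. With library totals alone as the scale, the median gene stood higher by 0.73 and 1.15 (log2) at 3 and 10 d on the control diet, by 0.80 and 1.31 on the folic acid diet, and by 0.39 and 0.50 at 10 d against 3 d. Levels are normalised counts (CPM).

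The first comparison asked what differed 3 d after castration on the control diet. Spink3 fell most and Car2 rose most of the named genes. Spink3, now named Spink1, a secreted protease inhibitor of the prostate (chromosome 18, 43728082 to 43737557), went from 12280 ± 3378 CPM (SD, n = 4) to 103 ± 46.0 (n = 3), a log2 change of -6.90 ± 0.36 (SE, adjusted p = 9.64e-15). Abo, a blood-group glycosyltransferase, fell by 5.41 ± 0.29. Car2, a carbonic anhydrase (chromosome 3, 14886273 to 14900770), rose from 35.8 ± 9.08 to 2272 ± 581 CPM (log2 change 5.99 ± 0.33, adjusted p = 2.20e-13). Cxcl5, a neutrophil-attracting chemokine (chromosome 5, 90759360 to 90761624), rose by 5.74 ± 0.56 from 1.22 ± 0.551 to 63.7 ± 25.3 CPM.

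The other largest rises at 3 d were Cxcl15, a lung-type chemokine, at 5.26 ± 0.44, Entpd8, an ectonucleotidase, at 4.57 ± 0.63, and Asgr1, a subunit of the asialoglycoprotein receptor, at 4.43 ± 0.40. Cadps followed at 3.98, Ces1e, a carboxylesterase, at 3.29 ± 0.40 and Car8 at 3.26 ± 0.23. The other largest falls were S1pr3, a sphingosine-1-phosphate receptor, at -5.17 ± 0.84, Rasd1 at -4.91 ± 0.89 and H2-Q10 at -4.68 ± 0.68. After them came Spin2d at -4.47 ± 0.70, Igfbp2, an insulin-like growth factor binding protein, at -4.44 ± 0.66 and Fkbp11 at -4.23 ± 0.51. Of the genes named in advance, Sbp fell by 1.49 ± 0.33, Fkbp5, an androgen-induced chaperone of steroid receptors, by 2.2 ± 0.23 and Mki67, the proliferation marker, by 3.08 ± 0.80. Pbsn, probasin, did not pass at -2.49 ± 1.29 (adjusted p = 0.271). Nor did Clu, clusterin, at 0.05 ± 0.78 (0.982), or Dnmt1 at -0.15 (0.790). Cadps no longer passed when any 1 of control intact replicates 1, 3 and 4 or control 3 d replicates 3 and 4 was left out (adjusted p from 0.0641 to 0.0852). Mki67 did not pass without control intact replicate 4 or control 3 d replicate 3 or 4 (0.0509 to 0.0881). Reads of Ces1e, H2-Q10, Spin2d and Cxcl5 can be shared with close relatives such as Ces1d or Spin2c.

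In all, 1339 genes changed at 3 d on the control diet (edgeR, adjusted p under 0.05), 514 upward and 825 downward. The genes of the secretory pathway and the unfolded protein response, which fold and export proteins, fell together. Of 71 tested 54 fell, 60 when adjusted over the list alone, none rose and 17 did not pass (median log2 change -1.12, camera adjusted p = 1.50e-64, and adjusted p = 8.17e-05 with an estimated correlation). Among them were Sdf2l1 at -3.08 ± 0.24, the chaperone Hspa5 (BiP) at -2.69 ± 0.25 and the disulfide isomerases Pdia4 at -1.90 ± 0.18 and P4hb at -1.93 ± 0.19. Of 35 prostate secretory and androgen-induced genes, 14 fell and 1, Igfbp3, rose, against 16 and 2 adjusted over the list alone (median -0.80, adjusted p = 1.65e-13, and 9.84e-05 with an estimated correlation). Folate transport and one-carbon metabolism fell with 9 of 42 genes lower and none higher, 11 and none adjusted over the list alone (median -0.45, adjusted p = 4.71e-06, and 0.000185 with an estimated correlation). The list fell through Mat2a, which makes S-adenosylmethionine, at -2.32 ± 0.20, Mthfd2 of the mitochondrial folate pathway at -2.66 ± 0.38, Cbs of transsulfuration at -2.10 ± 0.29 and Phgdh of serine synthesis at -1.73 ± 0.19.

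Further groups moved at 3 d on the control diet with the preset correlation but not with an estimated one. In polyamine metabolism Adi1, Odc1, Srm, Amd1 and Arg2 fell and Sat1, which breaks polyamines down, rose by 1.63 ± 0.21 (7 lower and 1 higher adjusted over the list alone, adjusted p = 0.000518, and adjusted p = 0.0686 with an estimated correlation). Cholesterol and fatty acid synthesis had 19 of 39 genes lower, such as Insig1 at -1.94 ± 0.24 and Cyp51 at -2.07 ± 0.26, and Acsl3 and Me1 higher (22 and 4 adjusted over the list alone, adjusted p = 1.83e-11, and adjusted p = 0.0615 with an estimated correlation). In the cell cycle list 9 of 60 genes fell, such as Rrm2 at -3.76 ± 0.55 and Top2a at -1.31 ± 0.31. Adjusted over the list alone 13 fell and 1 rose (adjusted p = 9.50e-08, and adjusted p = 0.203 with an estimated correlation). Macrophage markers rose in 6 of 26 cases, among them Ctss at 1.51 ± 0.26, Mpeg1 at 1.70 ± 0.32 and Lyz2 at 2.26 ± 0.42 (12 adjusted over the list alone, adjusted p = 9.84e-08, and adjusted p = 0.0615 with an estimated correlation). Steroid receptors and their cofactors had 5 of 17 higher both ways, among them Hsd17b11, Nr3c2, Ncoa3 and Nr3c1 (adjusted p = 0.00767, and adjusted p = 0.212 with an estimated correlation). Of the 28 genes chosen as known to rise after castration, 7 rose, such as Sat1 and Gas6, and Igfbp2 and Ctgf fell (8 and 2 adjusted over the list alone, adjusted p = 0.00767, and adjusted p = 0.281 with an estimated correlation). Cell death genes were not called as a list (adjusted p = 0.225). Of 41, Trp53inp1, Bnip3l and Casp6 rose and Cycs fell, with 3 and 1 adjusted over the list alone.

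**Figure D2:**
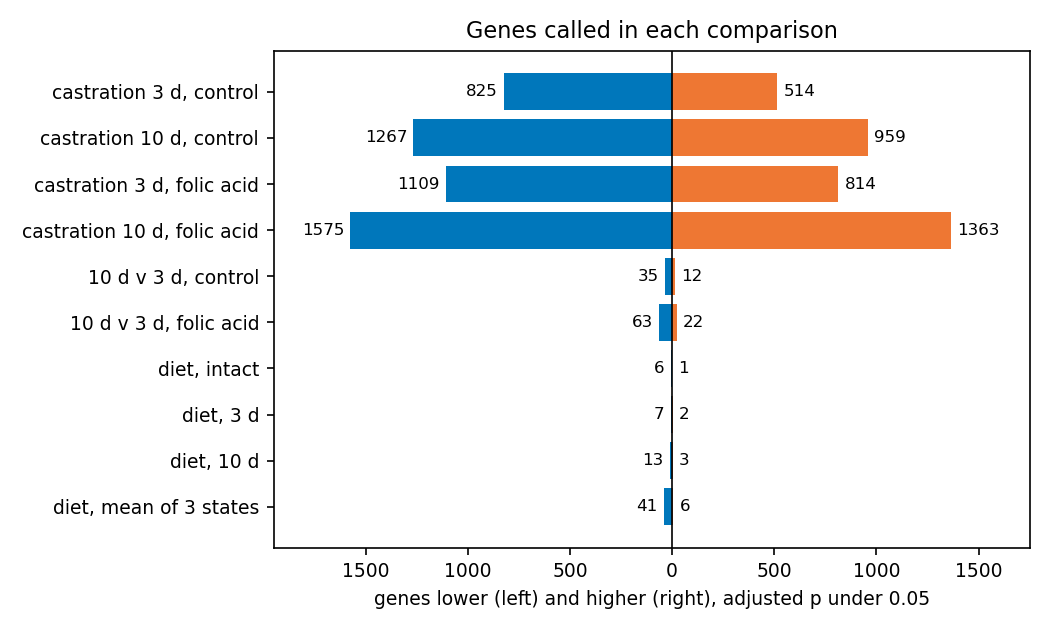
Number of genes called (edgeR, adjusted p under 0.05) higher and lower in each comparison except the diet by castration interactions. The castration comparisons called 1339 to 2938 genes, 10 d against 3 d called 47 and 85, and the diet comparisons 7 to 47.

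By 10 d on the control diet Spink3 and Abo were again among the genes that fell most, and the chemokine Cxcl5 had the largest rise of the named genes. Spink3 fell to 11.3 ± 1.56 CPM (n = 4), a log2 change of -10.08 ± 0.36 (adjusted p = 1.35e-19), and Abo fell by 6.80 ± 0.28. Cxcl5 rose by 8.77 ± 0.59 to 522 ± 258 CPM and Car2 by 7.02 ± 0.34. Other large rises were Asgr1 at 5.33 ± 0.39, Entpd8 at 5.02 ± 0.62, and Lars2, a mitochondrial leucyl-tRNA synthetase, at 4.89 ± 0.79. Cxcl15 was at 4.39 ± 0.42, Ces1d at 4.04 ± 0.34 and the sphingosine kinase Sphk1 at 3.91 ± 0.50. Other large falls were S1pr3 at -5.74 ± 0.77, H2-Q10 at -5.62 ± 0.64, Wfdc3 at -5.58 ± 1.38 and the proton pump subunit Atp6v1c2 at -5.46 ± 0.66. The skeletal muscle genes Myh1 and Acta1 were at -9.05 ± 2.64 and -5.93 ± 1.0. The muscle transcripts stood high in 1 intact library, control replicate 2, without which Myh1 was at -4.96 (adjusted p = 0.195) and Acta1 at -4.10 (0.000536). Myh1 also no longer passed when any 1 of control 10 d replicates 1 to 4 was left out (0.0648 to 0.0667).

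At 10 d on the control diet 2226 genes changed, 959 upward and 1267 downward. The secretory pathway fell with 61 of 71 genes lower, such as Edem1 at -1.78 ± 0.14 and Herpud1 at -1.89 ± 0.15 (63 lower and 1 higher adjusted over the list alone, adjusted p = 1.89e-57, and 9.94e-05 with an estimated correlation). Prostate secretory genes fell in 17 of 35 cases and Igfbp3, Chka, Tmprss2 and Sord rose (18 and 5 adjusted over the list alone, adjusted p = 1.30e-21, and 1.43e-05 with an estimated correlation). In one-carbon metabolism 12 of 42 genes fell, among them Mat2a at -3.15 ± 0.19, Mthfd2 at -3.62 ± 0.36 and Gnmt at -2.68 ± 0.33. Ggh and Tyms rose (13 and 3 adjusted over the list alone, adjusted p = 6.07e-05, and 0.000541 with an estimated correlation). Cell cycle genes fell in 21 of 60 cases, among them Mki67, and Mcm6 rose (31 and 1 adjusted over the list alone, adjusted p = 6.35e-09, and adjusted p = 0.186 with an estimated correlation). Cholesterol and fatty acid synthesis had 12 genes lower and Stard4 and Acsl3 higher (15 and 2 adjusted over the list alone, adjusted p = 0.000226, and adjusted p = 0.334 with an estimated correlation). Polyamine metabolism had 6 lower, with Sat1 and Sms higher, both ways (adjusted p = 0.00226, and adjusted p = 0.179 with an estimated correlation). The macrophage markers Ctss, Ms4a7, Lyz2, C1qa and C1qb rose, 7 adjusted over the list alone. So did the MHC class II genes H2-Ab1, Cd74, H2-Aa and H2-Eb1, 4 adjusted over the list alone (adjusted p of the lists p = 0.000226 and 0.0145, and adjusted p = 0.192 each with an estimated correlation). With library totals alone the cholesterol and fatty acid call (0.0782) and the macrophage call (0.52) ended, and the MHC class II list turned downward without a call (0.949).

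On the folic acid diet Spink3 again fell most of the named genes, and the largest rise was that of Car2 at 3 d and of Cxcl5 at 10 d. At 3 d Spink3 fell by 7.19 ± 0.32 from 19170 ± 2799 to 131 ± 43.7 CPM (n = 4 each). S1pr3 was at -5.31 ± 0.78, Abo at -4.98 ± 0.25 and Crabp1, a retinoic acid binding protein, at -4.84 ± 0.33. H2-Q10 was at -4.45 ± 0.60, Pdlim2 at -4.21 ± 0.43, the mitotic gene Birc5 at -4.10 ± 0.78 and the vesicular nucleotide transporter Slc17a9 at -3.95 ± 0.56. Car2 rose by 5.25 ± 0.32, Cxcl15 by 4.17 ± 0.41, Cxcl5 by 3.74 ± 0.65 and Entpd8 by 3.60 ± 0.60. Dcdc2a rose by 3.52 ± 0.68, Ces1d by 3.44 ± 0.33, Gpr128 (now Adgrg7) by 3.40 ± 0.44 and Acss3 by 3.35 ± 0.68. At 10 d Spink3 stood at -10.34 ± 0.37, Abo at -6.03 ± 0.27, Crabp1 at -5.70 ± 0.35 and Spink5 at -5.65 ± 0.60. H2-Q10 stood at -5.39 ± 0.63, Spin2d at -5.33 ± 0.66, the ribonucleotide reductase subunit Rrm2 at -5.25 ± 0.54 and S1pr3 at -5.21 ± 0.76. The largest rises at 10 d were Cxcl5 at 7.84 ± 0.62, Car2 at 6.10 ± 0.33, Lars2 at 4.51 ± 0.77 and the iron exporter Slc40a1 at 4.12 ± 0.85. Slc40a1 stood at 354 CPM in folic acid 10 d replicate 2 against 17.1 to 28.9 in the other 3 libraries, and without that library its change was 1.83 (adjusted p = 0.000157). In a fit of only the groups compared Slc40a1 was not called (log2 change 4.14, edgeR adjusted p = 0.0879). Asgr1 was at 4.07 ± 0.33, the transporter Slc16a11 at 3.92 ± 0.46, Igfbp3 at 3.90 ± 0.52 and Cxcl15 at 3.77 ± 0.41.

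On this diet 1923 genes changed at 3 d, 814 upward and 1109 downward, and 2938 at 10 d, 1363 upward and 1575 downward. The secretory pathway fell at both times. It had 50 and 56 of 71 genes lower, none higher at 3 d and Ero1l higher at 10 d (52 and 59 lower and 0 and 2 higher adjusted over the list alone). Prostate secretory genes fell in 15 and 18 of 35 cases, while Igfbp3 rose at 3 d and Igfbp3, Sord and Ndrg1 at 10 d (15 and 21 lower and 3 and 4 higher adjusted over the list alone). One-carbon genes fell in 12 of 42 cases at each time, and Ggh and Atic rose at 10 d (13 and 14 lower and 1 and 3 higher adjusted over the list alone), with Mat2a at -2.11 ± 0.18 and -2.89 ± 0.19. Polyamine genes fell in 6 and 7 of 19 cases and Sat1 rose at both times, joined by Sms at 10 d (8 and 9 lower and 1 and 2 higher adjusted over the list alone). These 4 lists were called with both correlations at both times. With an estimated correlation adjusted p was 0.000682 and 0.000458 for the secretory pathway and the same for one-carbon metabolism. It was 0.000196 and 5.06e-06 for the prostate list and 0.0448 and 0.0181 for polyamines. With library totals alone the polyamine call ended at both times (0.0547 and 0.0586), as it did on the control diet (0.0902 and 0.332). Cholesterol and fatty acid synthesis fell with 25 and 26 of 39 genes lower, Elovl7 higher at 3 d and Acsl3, Elovl7 and Stard4 higher at 10 d (26 and 28 lower and 2 and 5 higher adjusted over the list alone, and adjusted p = 0.00802 and 0.0538 with an estimated correlation). Cell cycle genes fell in 30 and 34 of 60 cases (39 and 41 adjusted over the list alone, and adjusted p = 0.0837 and 0.0904 with an estimated correlation). Macrophage markers rose in 4 and 9 of 26 (4 and 11 adjusted over the list alone, and adjusted p = 0.384 and 0.163 with an estimated correlation). The macrophage call ended with library totals alone (0.498 and 0.448). A fit left out 4 libraries: control intact replicate 2, high in muscle transcripts, folic acid intact replicate 3, with the lowest stromal score of all, and folic acid 10 d replicates 2 and 3, with the highest and lowest stromal score of their group. Without them 1327 genes were called at 10 d, 1262 of them shared with the 2938. Without folic acid intact replicate 2, 1272 genes were called at 3 d.

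**Figure D3:**
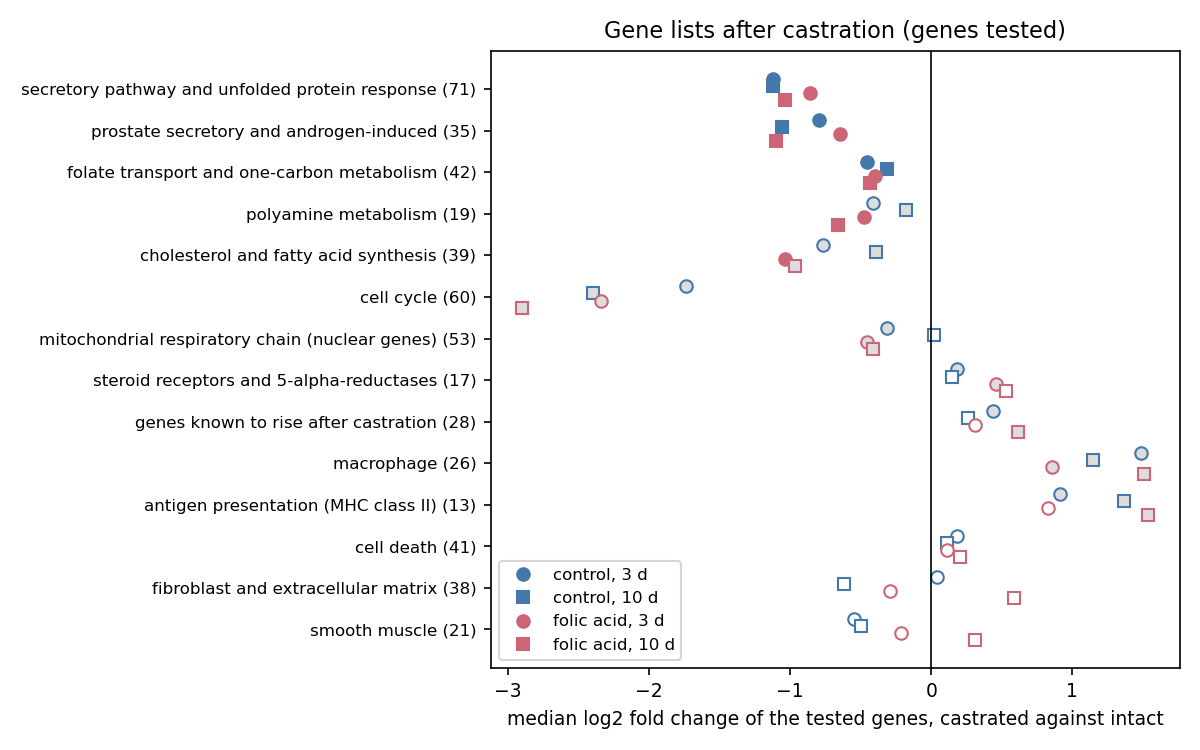
Median log2 fold change of the tested members of each gene list in the 4 castration comparisons. Filled symbols mark lists called by camera also with an estimated correlation, grey ones lists called with the preset correlation alone and white ones lists not called. The secretory pathway lies between -0.86 and -1.12 in all 4.

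Most genes called after castration on the control diet moved the same way on folic acid. Over the 13412 genes the log2 changes of the diets had a Pearson r of 0.464 and a Spearman rho of 0.543 at 3 d, and 0.579 and 0.636 at 10 d. These are descriptions across genes, which are not independent replicates. At 3 d 313 genes rose on both diets (31.2 by chance), 597 fell on both (68.2 by chance) and 1 was called in opposite directions. At 10 d 620 rose on both (97.5 by chance), 952 fell on both (149 by chance) and 1 was called in opposite directions. Of the genes called on the control diet, 98.0% at 3 d (1312 of 1339) and 98.3% at 10 d (2189 of 2226) had the same sign on the folic acid diet.

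Between 3 and 10 d Spink3 and Spink5 went on falling on both diets, and Lars2 and Cxcl5 rose. On the control diet Spink3 fell by a further 3.18 ± 0.28, Sbp by 2.28 ± 0.32 and Spink5 by 2.83 ± 0.55. The matrix gene Mfap4 fell by 2.35 ± 0.47 and Bgn by 2.33 ± 0.40. Lars2 rose by 5.33 ± 0.91, Cxcl5 by 3.04 ± 0.47, and Idi1 and Cyp51 of cholesterol synthesis by 1.90 ± 0.34 and 1.61 ± 0.26. On the folic acid diet Spink5 fell by 3.39 ± 0.54, Rrm2 by 3.37 ± 0.52, BC024139 by 3.26 ± 0.71, Spink3 by 3.15 ± 0.27 and Gabra4, a GABA receptor subunit, by 2.21 ± 0.37. Lars2 rose by 5.57 ± 0.81, Cxcl5 by 4.10 ± 0.45, the matrix gene Lum by 2.72 ± 0.63, Prodh by 2.28 ± 0.46 and Gpc3 by 2.02 ± 0.47.

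On the control diet 47 genes changed between 3 and 10 d, 12 upward and 35 downward, and on the folic acid diet 85, 22 upward and 63 downward. The prostate secretory list fell on both diets, with 9530002B09Rik, Spink3, Sbp and Abo lower on both and Azgp1 and Bmpr1b lower also on the folic acid diet (7 and 13 lower and 0 and 5 higher adjusted over the list alone, and adjusted p = 0.00123 and 0.000792 with an estimated correlation). Cholesterol and fatty acid synthesis had Cyp51, Insig1 and Idi1 among the genes higher on both diets and Sqle higher and Scd1 lower on the control diet (10 and 5 higher and 1 and 1 lower adjusted over the list alone, adjusted p = 0.00028 and 0.0392, and adjusted p = 0.781 and 0.629 with an estimated correlation). On the folic acid diet this list was not called without 3 d replicate 2 (0.126), 3 d replicate 4 (0.0503) or 10 d replicate 1 (0.577). Fibroblast and matrix genes as a list were lower on the control diet (median -0.62, Mfap4 alone called) and higher on the folic acid diet (median 0.71, Dcn and Lum called), with adjusted p = 0.868 and 0.595 with an estimated correlation. On the folic acid diet endothelium and macrophage lists were higher as well (medians 0.84 and 0.69, adjusted p = 0.013 and 0.00229, and adjusted p = 0.595 and 0.391 with an estimated correlation, no gene called). Polyamine, cell cycle and secretory pathway lists were also called downward there with the preset correlation, and genes known to rise after castration upward. With an estimated correlation these 4 lists had a camera adjusted p of 0.391, 0.629, 0.391 and 0.391. With library totals alone the fibroblast, endothelium and macrophage calls ended (0.292, 0.971 and 0.376). The endothelium call also ended without 3 d replicate 2 (0.134) or 10 d replicate 2 (0.524), and the macrophage call without the latter (0.091). Lars2 was much lower in control 10 d replicate 3, at 264 CPM, than in the other 7 libraries of 10 d, at 1280 to 8540. In a fit of only the groups compared, the calls of Lars2 on the control diet (0.275) and of Lum, Spink5, Rrm2, BC024139 and Gabra4 on the folic acid diet (0.0533 to 0.19) ended. On the control diet Lars2 no longer passed when any 1 of the 3 d replicates was left out (adjusted p from 0.0602 to 0.0903). Neither did Idi1 without 3 d replicate 4 (0.0568) or Mfap4 without 3 d replicate 3 (0.0827) or 10 d replicate 1 (0.0642). Spink5 did not pass without any 1 of the 3 d replicates or of 10 d replicates 1, 2 and 4 (0.0570 to 0.121). On the folic acid diet Lum no longer passed without any 1 of 3 d replicates 1 to 4 or 10 d replicates 1, 2 and 4 (0.0553 to 0.132). Neither did Gpc3 without 3 d replicate 2, 3 or 4 or 10 d replicate 2 or 4 (0.0740 to 0.164), nor Prodh without 3 d replicate 1 or 3 or 10 d replicate 2 (0.0568 to 0.0848) and BC024139 without 3 d replicate 3 (0.107) or 10 d replicate 2 (0.0713). The counts fell to 30, 28 and 30 on the control diet without 3 d replicate 3, 3 d replicate 4 or 10 d replicate 1. On the folic acid diet they were 48, 52, 43 and 53 without 3 d replicate 2, 3 d replicate 3, 10 d replicate 2 or 10 d replicate 4, and 167 and 137 without 10 d replicate 1 or 3.

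The diets were compared within each state and as the mean over the 3 states, the question being what a folic acid-enriched diet changes in the gland and in its response to castration. A small set of genes differed between the diets, most of them lower on folic acid, and none of them was in the list of folate transport and one-carbon metabolism. Averaged over the states, Il13ra1, a receptor subunit for interleukin-13 (chromosome X, 36112110 to 36171259), was lower by a log2 change of -1.33 ± 0.13 (adjusted p = 8.17e-08). Its level in intact, 3 d and 10 d glands was 78.2 ± 21.3, 75.7 ± 19.6 and 74.1 ± 13.2 CPM on the control diet and 18.0 ± 4.47, 34.2 ± 7.93 and 44.5 ± 5.26 on the folic acid diet (SD, n = 4, 3 and 4, and 4 each). Gipc2 (chromosome 3, 152093533 to 152166230) was at -1.76 ± 0.19, Fabp5, a fatty acid binding protein (chromosome 3, 10012548 to 10016607), at -1.62 ± 0.17, and Crabp1 (chromosome 9, 54764748 to 54773110) at -1.55 ± 0.18. Lower as well were Ank, a pyrophosphate exporter, at -1.37 ± 0.15, the mechanosensitive channel Piezo2 at -1.23 ± 0.15, Tsc22d3, a glucocorticoid-induced regulator, at -0.88 ± 0.11 and Memo1 at -0.87 ± 0.11. Pdzk1, a scaffold for membrane transporters (chromosome 3, 96829284 to 96870926), was higher by 1.27 ± 0.13 (adjusted p = 6.71e-07) and Asgr1 by 1.25 ± 0.20.

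For the mean over the states 47 genes were called, 41 lower and 6 higher on the folic acid diet, and 46 of them had the same sign in all 3 states. They were chosen on the mean of these same states, which favours a shared sign. Of the 47, 23 were also called in at least 1 state and 7 in at least 2. Besides Pdzk1 and Asgr1, Tmem191c at 0.81 ± 0.18, Papss2 at 0.48 ± 0.11, the noradrenaline transporter Slc6a2 at 0.55 ± 0.12 and Gpr155 at 0.51 ± 0.12 were higher. Their calls ended when any 1 of 9, 11, 17 and 19 of the 23 libraries was left out (adjusted p up to 0.0803, 0.0966, 0.104 and 0.139). Of the 47 genes 39 kept their call with a stromal score as covariate, and 11 lay on chromosome 3. Tmem191c, Papss2, Slc6a2 and Gpr155 were among those that lost it with the covariate (edgeR adjusted p from 0.0637 to 0.102). Of the genes named in advance, none of these passed for the mean over the states: Spink3 at 0.46 ± 0.15 (adjusted p = 0.312), Sbp at 0.35 ± 0.18 (0.722) and Clu at 0.80 ± 0.43 (0.751). Mki67 was at 0.84 ± 0.44 (0.735), Fkbp5 at 0.06 ± 0.12 (0.965), Pbsn at -0.94 ± 0.65 (0.836) and Dnmt1 at -0.04 ± 0.14 (0.983). Clu was high in folic acid 10 d replicate 2 alone, and without that library its mean difference was -0.00684. None of these genes passed within a state either.

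**Figure D4:**
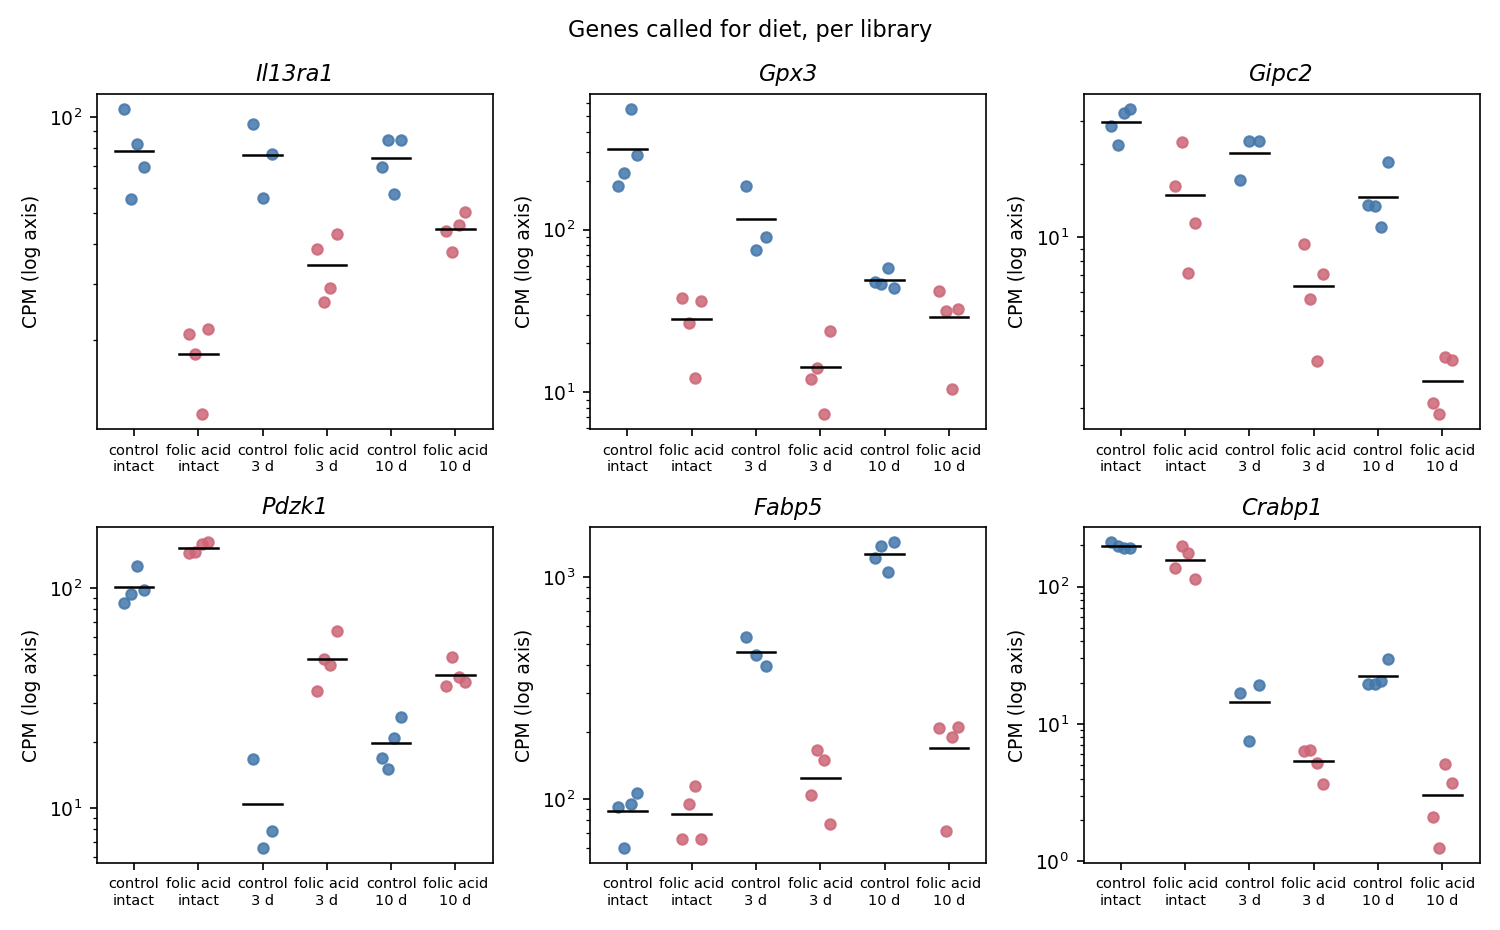
Normalised counts (CPM, log axis) of 6 of the genes that differed between diets, in each library, by state and diet, with group means as lines. Fabp5 had means of 88.5, 459 and 1267 CPM in intact, 3 d and 10 d glands on the control diet and 85.0, 124 and 170 on the folic acid diet.

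In intact glands 7 genes differed between diets. Gpx3, a secreted glutathione peroxidase (chromosome 11, 54902453 to 54910377), was lower on folic acid with a log2 change of -3.47 ± 0.49, at 28.3 ± 11.8 against 315 ± 167 CPM (n = 4 each, edgeR adjusted p = 0.00722). Chn1 was at -2.50 ± 0.49, Il13ra1 at -2.12 ± 0.22, Ank at -1.77 ± 0.25, Tsc22d3 at -1.02 ± 0.18 and Pdia4 at -0.78 ± 0.15, and Asgr1 was higher by 2.35 ± 0.42. The count was 48 without folic acid intact replicate 4, 3 without folic acid intact replicate 3 and 4 without control intact replicate 1, 3 or 4. Of the calls 4 each ended without several single libraries: Asgr1 without control intact 1 or 4 or folic acid intact 2 or 3 (adjusted p from 0.0582 to 0.0939), and Tsc22d3 without control 3 or folic acid 1 or 3 (0.0573 to 0.0756). Chn1 was not called without control 1, 3 or 4 or folic acid 1 or 3 (0.0761 to 0.168), and Pdia4 without any control library or folic acid 2 or 3 (0.0662 to 0.361). With only the groups compared Asgr1 (0.489), Gpx3 (0.0997), Chn1 (0.34) and Pdia4 (0.0743) were not called.

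At 3 d after castration 9 genes differed. Pdzk1 was higher on folic acid by 2.18 ± 0.26 (47.4 ± 12.3 against 10.4 ± 5.52 CPM, n = 4 and 3, adjusted p = 1.89e-05) and Gpr155 by 1.24 ± 0.22. Fabp5 was lower at -1.89 ± 0.30, Gpx3 at -3.02 ± 0.51, Cxcl5 at -2.78 ± 0.45 (9.22 ± 4.19 against 63.7 ± 25.3 CPM), and Gipc2 at -1.81 ± 0.34. Lower too were the signalling factor Stat5a at -1.54 ± 0.27, Il13ra1 at -1.15 ± 0.22 and Tsc22d3 at -1.04 ± 0.19. As many genes were called in 3 of the 35 splits of these 7 libraries, the real one included. The count fell to 4 without control 3 d replicate 4 and to 2 without folic acid 3 d replicate 2 or 3, and the calls that stayed without each of these 7 libraries were those of Pdzk1 and Fabp5. The others ended without folic acid 3 d replicate 2 (adjusted p from 0.0664 to 0.208) and without replicate 3 (0.0734 to 0.154). Besides, Gpr155, Tsc22d3, Gpx3 and Il13ra1 did not pass without control 3 d replicate 1 (0.0630 to 0.322) and Gpr155 and Gipc2 without replicate 3 (0.129 and 0.0679). The same held for Tsc22d3, Gipc2, Cxcl5, Gpx3 and Il13ra1 without replicate 4 (0.0572 to 0.119), and Cxcl5, Gpx3 and Il13ra1 without folic acid 3 d replicate 1 (0.0603 to 0.134). The call of Gpx3 also ended with only the groups compared (0.107).

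At 10 d 16 genes differed, 13 lower and 3 higher on folic acid. Fabp5 was lower at -2.90 ± 0.29, at 170 ± 66.3 against 1267 ± 171 CPM (n = 4 each, edgeR adjusted p = 7.18e-06). Crabp1 was at -2.90 ± 0.32, at 3.06 ± 1.72 against 22.3 ± 4.89 CPM. Further genes were Gipc2 at -2.50 ± 0.34, Piezo2 at -1.54 ± 0.26, Memo1 at -1.39 ± 0.19, the zinc transporter Slc39a8 at -1.03 ± 0.17, the polymerase subunit Rev3l at -0.98 ± 0.18 and Phlda1 at -0.94 ± 0.18. Higher were 9530002B09Rik, a prostate secretory list gene, at 1.52 ± 0.27, Slc6a2 at 1.19 ± 0.21 and Pdzk1 at 1.03 ± 0.22. The call of Pdzk1 ended without any 1 of control 10 d replicates 1, 2 and 3 or folic acid 10 d replicates 2, 3 and 4 (adjusted p from 0.0870 to 0.237). That of Phlda1 ended without control 10 d replicate 1 or 4 or folic acid 10 d replicate 2 or 4 (0.0800 to 0.10), and those of Slc6a2 and Rev3l without control 10 d replicate 1 (0.0521 each). The count was 9 without control 10 d replicate 1 and 10 without replicate 3. In a fit of only the groups compared it was 4, and the calls of Piezo2 (0.331), Slc39a8 (0.151), Rev3l (0.151), Phlda1 (0.158), Slc6a2 (0.226) and Pdzk1 (0.197) ended.

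In folate transport and one-carbon metabolism none of the 42 tested genes was called in any state or for the mean over the states, also adjusted over the list alone, and the list was not called (adjusted p from 0.459 to 0.993). In DNA methylation and demethylation none of 21 was called either way (0.279 to 0.749). With the preset correlation 8, 3, 8 and 4 lists were called in intact, 3 d, 10 d and mean comparisons, and none of them with an estimated correlation. They included fibroblast and matrix genes at 3 d (median -0.90, adjusted p = 2.06e-14, and adjusted p = 0.66 with an estimated correlation), cholesterol and fatty acid synthesis at 10 d (median -0.39, 8 of 39 genes lower and none higher adjusted over the list alone, none over all genes, adjusted p = 1.31e-10, and adjusted p = 0.314 with an estimated correlation). A further one was the secretory pathway in intact glands (median -0.20, 6 lower and none higher adjusted over the list alone, Pdia4 over all genes, adjusted p = 8.34e-09, and adjusted p = 0.30 with an estimated correlation). Cell-type lists moved in the same comparisons with the preset correlation. In intact glands smooth muscle and fibroblast genes were lower and luminal and proximal luminal genes higher, at 3 d macrophage markers were lower, and at 10 d luminal genes were lower and fibroblast and endothelium genes higher (medians -0.34, -0.60, 0.14, 0.22, -0.82, -0.17, 0.48 and 0.70). Without folic acid intact replicate 3 the intact smooth muscle and fibroblast calls ended (adjusted p = 0.65 and 0.201), the former also without control intact replicate 2 (0.14). The intact proximal luminal call ended without control intact replicate 3 (0.063) or folic acid intact replicate 4 (0.0569). That of the intact luminal list ended with library totals alone (0.0937) and in the fit without 4 libraries (0.0542). Without folic acid 10 d replicate 2 those of luminal, fibroblast and endothelium genes at 10 d ended (0.0622, 0.441 and 0.73), as they did without control 10 d replicate 1 (0.282, 0.282 and 0.149). The luminal and endothelium calls at 10 d ended without control 10 d replicate 2 (0.0541 and 0.0522), and the luminal one without folic acid 10 d replicate 4 (0.204). The stromal score, the mean log2 CPM of smooth muscle, fibroblast and endothelial genes, was 0.865 in folic acid intact replicate 3, 4.23 in folic acid 10 d replicate 2, 1.97 in folic acid 10 d replicate 3 and 1.86 to 3.82 in the other 20 libraries.

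Whether the response to castration itself differed between diets was tested by the interaction. At 10 d the rise of Fabp5 was smaller on folic acid and the fall of Crabp1 larger. Fabp5 rose by 3.84 ± 0.31 on the control diet and by 1.0 ± 0.28 on folic acid (interaction -2.84 ± 0.40, adjusted p = 0.00255). Crabp1 fell by 3.15 ± 0.29 and 5.70 ± 0.35 (interaction -2.55 ± 0.42, adjusted p = 0.0172). These were the 2 genes called at 10 d. In 5 of 100 regroupings of the libraries, the real one included, as many genes were called. The interaction of Crabp1 no longer passed without control intact replicate 3 or 4, folic acid intact replicate 2 or 3, control 10 d replicate 4 or folic acid 10 d replicate 1 (adjusted p from 0.0549 to 0.101), each of which left 1 gene. At 3 d no gene passed in edgeR. Of 13412 genes 650 had an unadjusted p under 0.05, no more than chance gives at that threshold. DESeq2 called 3 genes (Kcnn4, Fabp5 and Pdzk1) and voom 2 (Kcnn4 and Fabp5). The genes with the smallest p were Kcnn4, a potassium channel, at -2.29 ± 0.41 (adjusted p = 0.0602), Pdzk1 at 1.59 ± 0.33 (0.217) and Eme2 at 1.75 ± 0.39 (0.408). Next were Fabp5 at -1.83 ± 0.40 (0.455) and Ppp1r1b at -1.40 ± 0.33 (0.531). Kcnn4 passed without folic acid intact replicate 4 (0.0413) or folic acid 3 d replicate 3 (0.0493), and Pdzk1 without control 3 d replicate 1 (0.00137). Of the lists, 8 were called at 3 d (1 upward, 7 downward) and 10 at 10 d (4 upward, 6 downward) with the preset correlation. With an estimated correlation 0 and 1 of them were called. That 1 was the luminal epithelium list, which had a lower response on folic acid at 10 d with both correlations (median -0.29, adjusted p = 0.000271, and 0.0495 with an estimated correlation), although none of its 22 genes was called, also adjusted over the list alone. In the same comparison smooth muscle, fibroblast and endothelium lists moved the other way with the preset correlation (medians 0.78, 0.96 and 0.92, adjusted p = 0.00133, 5.53e-09 and 0.00322, and adjusted p = 0.597, 0.496 and 0.597 with an estimated correlation). The smooth muscle and endothelium calls ended without folic acid intact replicate 3 (0.0617 and 0.0517) or folic acid 10 d replicate 2 (0.246 and 0.177).

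An involution score summed up the response in each library as the mean log2 CPM of 326 genes higher after castration minus that of 445 genes lower, chosen without regard to diet. On the control diet it moved from -3.17 ± 0.110 in intact glands to 0.482 ± 0.210 at 3 d and 0.877 ± 0.0792 at 10 d. The folic acid score went from -3.24 ± 0.231 to 0.192 ± 0.109 and 0.865 ± 0.254 (SD, n = 4, 3 and 4, and 4 each). The diets differed by -0.0759 in intact glands (exact permutation p = 0.686, adjusted p = 0.899), by -0.291 at 3 d (exact permutation p = 0.0857, adjusted p = 0.428, smallest possible p = 0.0286) and by -0.0116 at 10 d (exact permutation p = 0.943). The change from intact to 3 d was 3.44 ± 0.128 (SE) on folic acid and 3.65 ± 0.133 on the control diet, a difference of -0.215 (exact permutation p = 0.310, adjusted p = 0.775). To 10 d it was 4.11 ± 0.172 and 4.05 ± 0.0676, a difference of 0.0643 (exact permutation p = 0.719, adjusted p = 0.899). None of these 5 differences passed. A difference within 1 state, alone at its smallest possible p of 0.0286, could not have passed after adjustment over the 5 tests. The sign of the intact and 10 d differences turned when single libraries were left out (0.0745 without folic acid intact replicate 3, and 0.0296, 0.0252, 0.00733, 0.0209 and 0.0656 without control 10 d replicate 2 or 4 or folic acid 10 d replicate 1, 3 or 4). So did that of the change to 10 d (-0.0623 and -0.0353 without folic acid intact replicate 3 or folic acid 10 d replicate 2).

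**Figure D5:**
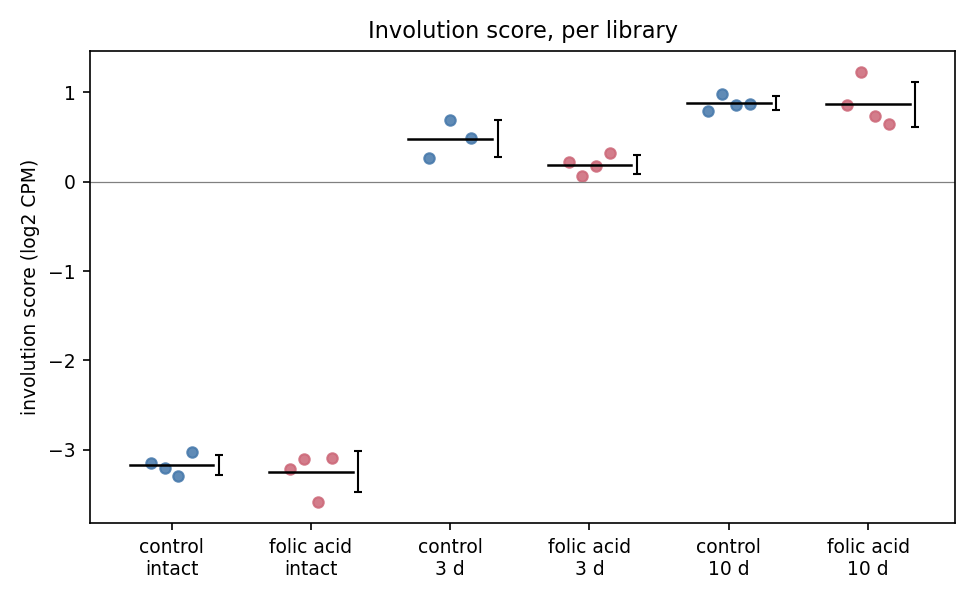
Involution score of each library (points, log2 scale) by diet and state, with the group mean (line) and SD (bar). At 3 d the means were 0.482 on the control diet and 0.192 on the folic acid diet, the widest gap between diets of the 3 states.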

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

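The tests of stromal content, of a mislabelled library, of ribosomal RNA, of carried-over muscle and of the fullest chromosome were chosen only after the result was seen, and the tests of chromosome neighbours and of a library batch were written before.

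In sets of 4 libraries of a group, a library was taken as far from the others when its gap to the nearest was over 0.83 of the range of the set. This held in 49 of 550 sets, where chance gives about 1 in 20, or 27.5. Of the 49, 11 lay in folic acid 10 d replicate 2 and 4 each in folic acid intact replicate 3 and control intact replicate 2, so single values here need not mean anything. Of the 49, 47 are listed below.

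Among library measures, the total count, in M reads, was 12.7 in folic acid 10 d replicate 1 (the others 7.51 to 8.39). Only 12627 genes had a count in folic acid 10 d replicate 3 (the others 13863 to 13979). Among list means (log2 CPM), folic acid intact replicate 3 was far below the rest of its group in fibroblast and matrix genes at 0.934, in endothelium at -1.11, in macrophage markers at 0.339 and in red blood cell genes at -0.192. Control intact replicate 2 was far above its group in skeletal muscle at 7.68, adipocyte at 3.89 and urothelium genes at 4.85. Folic acid 10 d replicate 2 stood apart in cell death at 3.71 and immediate-early genes at 3.93. So did folic acid 3 d replicate 2 in smooth muscle at 3.58 and immediate-early genes at 3.82. Single libraries also stood apart in one-carbon metabolism (control intact replicate 3 at 3.97, control 10 d replicate 3 at 3.27, folic acid 10 d replicate 1 at 3.45). This held too for DNA methylation (folic acid 3 d replicate 3 at 3.83), MHC class II (control 10 d replicate 2 at 1.81), skeletal muscle (folic acid 3 d replicate 3 at 1.56) and red blood cell genes (control intact replicate 3 at 0.0777).

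Among named genes (CPM), folic acid 10 d replicate 2 was far from its group in Clu at 3101, Slc40a1 at 354, Pdia4 at 86.2, Memo1 at 71.8, Fabp5 at 71.4, Ces1d at 54.4, Cadps at 39.1, Stat5a at 32.2 and Sphk1 at 15.3. In intact control glands the far values were S1pr3 at 51.6 and Bgn at 33.7 in replicate 3 and Acta1 at 874 in replicate 2. In intact glands on folic acid they were Phlda1 at 174, Car8 at 12.1 and Slc16a11 at 0.345 in replicate 2, Igfbp2 at 35.4 in replicate 4 and Ppp1r1b at 45.6 in replicate 1. At 3 d on folic acid they were Gpr155 at 110 and Ces1d at 56.8 in replicate 4, Myh1 at 36.2 in replicate 3 and Lum at 0.675 in replicate 2. At 10 d on the control diet they were Lars2 at 264 and Rrm2 at 0.43 in replicate 3, and Stat5a at 16.2 in replicate 2. Replicate 4 was far from the others in Crabp1 at 29.5, Gabra4 at 9.82 and Myh1 at 1.31.

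The interaction of diet and castration at 10 d passed for Fabp5 (-2.84) and Crabp1 (-2.55), but chance cannot be excluded for a count of 2. The Crabp1 call ended with voom (adjusted p = 0.0515), with the replicate block (0.098) and without any 1 of 6 libraries (0.0549 to 0.101).

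The genes called for the mean effect of diet were mostly lower on folic acid (41 of 47). With the stromal score as covariate 39 of the 47 stayed called. Those that did not included Tmem191c, Papss2, Slc6a2 and Gpr155, all higher on folic acid (edgeR adjusted p from 0.0637 to 0.102). Over the 47 genes the median ratio of the changes after to before was 0.98 (0.855 to 1.1), which argues against lower stromal content as the whole cause. The called genes formed 14 pairs within 5 Mb, against a median of 6 and a 95th percentile of 11 in random sets (134 of 10000 sets had as many). On chromosome 3 lay 11 of the 47 (2.29 expected, 27 of 10000 random sets had a chromosome as full), among them Pet112, Fam160a1, Glt28d2 and Sh3d19 within 0.397 Mb. These neighbours all pair with one another, so the pairs are not independent. The 11 genes ranged from position 10012548 to 152166230, so 1 short segment would not hold them all. The same number of top castration genes formed up to 12 pairs, within counting spread of 14, so co-change of neighbours cannot be told apart from the segment, and the limit for this comparison was revised after the values were seen. A chromosome segment that differs between the mice of the diets is a candidate explanation for part of the genes, and an effect of the diet itself stays open as well.

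Lars2 stood at 1280 to 8540 CPM (median 4300) in 7 of the 8 libraries of 10 d and at 264 in control 10 d replicate 3, against 54.8 to 279 in the 15 intact and 3 d libraries. A mislabelled library of an earlier time is argued against by the Sbp share of that replicate, 6.24%, which lay within the other 10 d libraries (4.78% to 16.2%) and below those of 3 d (26.2% to 38.8%). A batch of many genes that replicate 3 does not share stays open: 0 genes other than Lars2 were called when it was split off (at most 1 for another library of the group), but Lars2 itself was not called there either (log2 change -4.38, adjusted p = 1), so the reading of this test was revised after the values were seen. Ribosomal RNA reads counted for Lars2 could not be tested with 0 ribosomal RNA genes in the table, and androgen loss stays open as a biological explanation.

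Control intact replicate 2 held skeletal muscle transcripts: 14 of 15 genes were at least 8-fold above the highest other library of its group, such as Tnnt3 at 885 CPM, Myh4 at 859 and Acta1 at 874. Carried-over muscle, a tissue next to the gland in dissection, is a candidate explanation, and the list mean was 7.68 against 0.0911 to 0.471 in the rest of the group. Without this library 992 genes were called at 3 d and 1796 at 10 d on the control diet, and the called muscle genes went from 4 to 1 and from 11 to 3. Both totals lay within the ranges found when other single libraries were left out, given below. The fall in all called genes is therefore not particular to this library. No biological explanation was tested, since the labels give none for a single mouse.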

How the results depend on the processing

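The fits without 4 libraries and with the stromal score as covariate were chosen only after the result was seen. The values of named genes were sorted by call, not by the size of the change. A gene called in both fits counted as the same if its direction held. A gene called in neither counted as the same if it shifted by under a standard error, whatever its sign, and otherwise as moved. Under the alternatives 6131 cases were the same, 126 lost the call, 93 gained it, 96 moved and 3 turned direction. With single libraries left out these were 5251, 243, 27, 50 and 0 cases. The called list tests kept direction and call in 386 cases, lost the call in 166 and reversed in 6, and with single libraries left out in 830, 91 and 1. TMM without the 50 most abundant genes left all 544 values in the same class. Groups of 3 or 4 libraries were also simulated, without a castration response. There 2-fold changes were called in 23.9% to 46.3% of cases in the castration comparisons on the control diet and 13.4% and 4.48% in the interactions. For all values below the cause was not tested, except that a fold minimum can only lower a count by construction.

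The replicate number as a replicate block, added although the labels pair nothing, gave 11 genes for diet in intact glands, 1 for the 10 d interaction and 5 lists for diet at 3 d. The score difference at 3 d was then -0.319 (permutation p = 0.0286). This p is not exact, because the block was removed with residuals taken within the true diet groups before the labels were permuted. It is therefore not read as a diet difference. Over 55 pairs of libraries with the same number in different groups, residuals had correlations from -0.149 to 0.237 (median 0.013, 5 above 0.1), so the numbers were not treated as paired.

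With library totals alone the castration counts were 5696 (5464 higher, 232 lower, against 514 and 825) and 9040 (8773 and 267) on the control diet. They were 6592 (6378 and 214) and 9870 (9678 and 192) on folic acid, and 1275 (1253 and 22) and 1974 (1942 and 32) at 10 d against 3 d. The median gene then moved by 0.731, 1.15, 0.798, 1.31, 0.391 and 0.50, and 10 lists were called at 10 d against 3 d on the control diet. With that scale the list tests of MHC class II at 10 d (adjusted p = 0.949 on the control diet, 0.566 on folic acid), the respiratory chain (0.481) and endothelium (0.112) at 10 d on folic acid, and endothelium at 10 d against 3 d on folic acid (0.971) turned direction. So did at 10 d on folic acid the changes of Anxa1 (0.335), Uqcrfs1 (0.134) and Cox5a (0.0739). Smooth muscle in intact glands turned without the 4 libraries (0.718), and the secretory pathway for diet at 10 d without folic acid 10 d replicate 2 (0.936). That list stayed called without folic acid 10 d replicate 3 (0.000149).

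voom called 2076 and 3586 genes at 3 and 10 d on the control diet, 34 for diet in intact glands and 34 at 10 d, and 2 in the 3 d interaction. DESeq2 called 152 and 261 at 10 d against 3 d on the control and the folic acid diet. It called 23, 27 and 44 for diet in the 3 states, 81 for the mean effect, and 3 and 9 in the interactions. A minimum absolute log2 change of 1 left 695 and 1085 on the control diet, 770 and 1425 on folic acid, 30 and 50 at 10 d against 3 d, and 19 for the mean effect. Without the 4 libraries 1327 were called at 10 d on folic acid, 42 at 10 d against 3 d on folic acid, and 4 and 22 for diet in intact glands and at 3 d. The lists called were 5 for diet at 3 d, 7 for the mean effect and 6 in the 10 d interaction. With only the groups compared, 20 genes were called at 10 d against 3 d on folic acid, 15 and 4 for diet at 3 and 10 d, and 1 in the 3 d interaction. No filter and the stromal score each gave 1 gene in the 3 d interaction. RLE factors gave 4 lists for diet at 10 d.

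With an estimated correlation 3, 3, 5, 4, 1, 1, 0, 0, 0, 0, 0 and 1 of 11, 8, 9, 11, 4, 9, 8, 3, 8, 4, 8 and 10 called lists remained in the 12 comparisons. Their order is castration at 3 and 10 d on the control and on the folic acid diet, 10 d against 3 d on each, diet in the 3 states and as the mean, and the interactions. With fry 1 and 1 lists were called at 10 d against 3 d, 0 in each diet comparison and 0 and 1 in the interactions.

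The score difference in intact glands was 0.0663 from genes lower after castration alone, 0.166 from 100 genes each way, 0.0999 from changes of at least 2 and 0.0457 without the 4 libraries. At 10 d it was 0.0282 and 0.0868 with the first 2 of these settings, 0.00471 with RLE and 0.0509 with library totals. The difference in the change to 10 d was -0.0381, -0.0788, -0.296 and -0.206 with the same 4 settings as in intact glands. The correlation of responses was 0.672 (rho 0.632) at 3 d and 0.755 at 10 d with the strict filter, and 0.871 (rho 0.902) and 0.834 (rho 0.909) over genes called without regard to diet. The latter genes were chosen in these same libraries for a change over both diets together. That choice favours genes that move alike, so these values do not show how alike the responses are.

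Leaving out single libraries gave 906 to 1135 and 1744 to 1970 genes after castration on the control diet, 1272 to 2143 and 2274 to 3054 on folic acid, and 28 to 52 and 43 to 167 at 10 d against 3 d. The ranges were 3 to 48, 2 to 10 and 9 to 24 for diet in the 3 states, 37 to 64 for the mean effect, and 0 to 2 and 1 to 3 in the interactions. The lists called ranged from 5 to 12 at 10 d against 3 d on folic acid, 5 to 10, 3 to 7 and 2 to 12 for diet in the 3 states and 2 to 6 for the mean effect. The score differences ranged from -0.156 to 0.0745 in intact glands, -0.35 to -0.171 at 3 d and -0.0961 to 0.0656 at 10 d. In the change they ranged from -0.312 to -0.113 and -0.0623 to 0.185. The correlations ranged from 0.371 to 0.496 and 0.516 to 0.622. The difference in the share of the 20 most abundant genes ranged from -21.5 to -20.9, -42.2 to -40.9, -25.0 to -20.6 and -44.9 to -40.5. No p under 0.05 was possible at 3 d on the control diet with 6 libraries.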

Other observations

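The counts of splits reported here, and the fits without 4 libraries, were chosen or read only after the result was seen, while the lists and their tests were fixed before.

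Epithelial, immune and vascular markers went several ways after castration. Of 22 luminal genes Dpp4 rose in all 4 castration comparisons and Prom1 in 3 of them, while Hoxb13, a prostate homeobox gene, fell in all 4 relative to the median gene. The luminal list was not called (adjusted p = 0.121, 0.242, 0.919 and 0.341 at 3 and 10 d on the control and 3 and 10 d on the folic acid diet). Nor were basal epithelium (0.804, 0.56, 0.859 and 0.705), where Trp63 rose by 1.2 ± 0.28 at 10 d on folic acid, or the castration-resistant proximal luminal list (0.438, 0.242, 0.258 and 0.53). In that last list Ppp1r1b rose by 1.2 ± 0.24 and 1.97 ± 0.23 on the control diet. Smooth muscle (0.281, 0.242, 0.814 and 0.484) and fibroblast and matrix genes (0.281, 0.123, 0.728 and 0.111) were not called. Lum and Dcn rose in 3 of the 4 comparisons and Col1a1 and Sparc fell at 10 d on both diets. Endothelium was called at 10 d on folic acid (median 1.15, adjusted p = 0.04, and adjusted p = 0.59 with an estimated correlation, Emcn higher). The call ended without folic acid intact replicate 3 (0.135), folic acid 10 d replicate 2 (0.278) or replicate 4 (0.0606), without the 4 libraries (0.109) and with fry (0.0878). It turned downward without a call with library totals alone (0.112).

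MHC class II genes at 3 d were called on the control diet (adjusted p = 0.0473, and adjusted p = 0.281 with an estimated correlation, Itgax higher) and not on folic acid (0.258). The call on the control diet ended with library totals alone (0.962), with RLE factors (0.0579) and without control intact replicate 2 or 3 or control 3 d replicate 1 or 4 (0.0629 to 0.0806). At 10 d on folic acid they were called with Cd74, H2-Eb1, H2-Aa and H2-Ab1 higher and H2-DMa lower (0.0435, and adjusted p = 0.38 with an estimated correlation). The list turned downward without a call with library totals alone (0.566), and the call ended without folic acid intact replicate 1 (0.0695) or 4 (0.0842) or folic acid 10 d replicate 2 (0.135). Lymphocyte genes were not called (0.282, 0.0657, 0.428 and 0.212), with Gzmb, granzyme B, higher at 10 d on both diets. The interferon list was not called (0.464, 0.882, 0.258 and 0.333), and Rsad2 fell in all 4 comparisons, by 1.76 ± 0.42, 3.31 ± 0.41, 1.97 ± 0.38 and 2.61 ± 0.39. Nuclear genes of the mitochondrial respiratory chain fell at 3 d on both diets and at 10 d on folic acid with the preset correlation. Of 53 genes 6, 18 and 18 were lower and none higher, and 6, 26 and 21 lower adjusted over the list alone (adjusted p = 2.64e-05, 1.19e-08 and 1.63e-05, and adjusted p = 0.461, 0.384 and 0.461 with an estimated correlation). With library totals alone the 3 d calls ended on both diets (0.597 and 0.101) and the 10 d list on folic acid turned upward without a call (0.481). With fry the 3 d call on the control diet ended (0.0521). The list was not called at 10 d on the control diet (0.758), and Ndufa1 fell in all 4. DNA methylation genes were not called as a list (0.83, 0.791, 0.814 and 0.874), and Uhrf1 fell at 10 d on the control diet and at both times on folic acid. The 10 d cell death list was not called on either diet (0.248 and 0.333), nor the 3 d one on folic acid (0.466).

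Of the lists for neighbouring tissue and sample quality, adipocyte (adjusted p = 0.913, 0.882, 0.945 and 0.644), nerve and Schwann cell (0.282, 0.599, 0.728 and 0.263), skeletal muscle (0.102, 0.07, 0.111 and 0.142) and immediate-early genes (0.622, 0.72, 0.111 and 0.375) were not called after castration. Fosl2 rose in all 4 comparisons, by 2.35 ± 0.21, 2.50 ± 0.20, 2.07 ± 0.20 and 2.04 ± 0.20. Too few genes were tested for 5 lists. There were 3 for neutrophil and mast cell, none of them called, and 4 for urothelium, where Upk1b rose in all 4 comparisons. There were 4 for red blood cell, where Hbb-bs fell at 3 d on folic acid, and 0 for seminal vesicle and for the mitochondrial genome.

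Other splits of the same libraries were counted for each number of called genes. A share of 1 in 35 is the smallest these splits allow. No share was adjusted over the 12 comparisons, so a share at that floor does not by itself exclude chance. For castration only 1 of 35 splits, the real one, called as many genes in each comparison. On the control diet these were 1339 against at most 262 in the others at 3 d and 2226 against 0 at 10 d. They were 1923 against 24 and 2938 against 133 on folic acid. The real split alone called as many genes also at 10 d against 3 d (1 of 35 splits each, 47 against 13 and 85 against 4). The same held for diet in intact glands (1 of 35, 7 against 1) and at 10 d (1 of 35, 16 against 6), and for the mean effect of diet (1 of 100, 47 against 27). Chance cannot be excluded for diet at 3 d, where 3 of 35 splits called as many as the real 9 and another split called 56. So many genes in another split point to a structure of these samples, and what separates the libraries there was not tested. Nor can it be excluded for the interaction at 10 d, where 5 of 100 regroupings called as many as the real 2 (at most 4). For the interaction at 3 d the real count was 0, which 100 of 100 regroupings (at most 3 genes) reach by construction, so they decide nothing.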
